A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

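RNA of 3 budding yeast deletion strains grown with 2% glucose was compared with wild-type RNA on 12 Agilent arrays, with 4 arrays per strain. Per the labels, the strains were a gcr1 null, a nup84 null and a nup84 gcr1 double null. RNA was amplified and labelled with an Agilent linear amplification kit. On arrays 1 and 2 of each strain the deletion strain was in Cy5 and the wild type in Cy3, and on arrays 3 and 4 the dyes were exchanged.

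The deposited values were read as log2 ratios of Cy5 over Cy3, 1 per probe and array. Neither the log base nor the direction is written in the table. The log2 scale was inferred from the values, and the direction was taken from the dyes in the labels together with NUP84, which lay below 0 in the strains labelled as lacking it once arrays 3 and 4 were turned. What the submitters did to scale, centre or correct the values before deposit is not given in the sources used here. Channel intensities were not analysed here, so dim and saturated spots could not be told from others.

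The table held 10807 probes. The platform annotation named 1 gene for 9271 of them, several genes for 0 and none for 1536, and the unnamed probes were kept out of the gene tests. All 9271 entrez identifiers matched the yeast gene table of assembly R64, and 0 symbols needed an update. The probes of a gene were averaged per array, which gave 5636 genes, all with a value on 12 arrays. Of these genes, 2026 had 1 probe, 3592 had 2 and 18 had more. The 2 probes of a gene differed by a median of 0.0488 in the mean log2 ratio of the strain labelled gcr1 null, with r = 0.991 across genes, and 2 genes had probes more than 1 apart. Genome coordinates are not printed because the array's genome build is not given in the sources used here. The deposited table held 0 columns of other series.

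Signs of arrays 3 and 4 were turned, so that every value was deletion strain over wild type. The median over genes then ranged from -0.163 to 0.099 between arrays. Because at least 1 median lay farther than 0.1 from 0, each array was centred on its median, by a rule fixed before the data were examined. The design text of the series describes biological replicates, each with a technical dye swap. The 4 arrays of a strain were therefore taken as 2 biological samples, and n = 2 stands for these samples throughout. Which arrays are swaps of each other is not labelled. Each gene was therefore tested on pair means under both possible pairings, arrays 1 with 3 and 2 with 4, and arrays 1 with 4 and 2 with 3. The larger p-value and the larger standard error (SE) of the 2 fits were kept. The SE is moderated and pooled over the 3 strains, so a gene has the same SE in each strain. The SD over genes of the difference between pair means was 0.497, 0.421 and 0.808 for the first pairing in the strains labelled gcr1 null, nup84 null and double null. It was 0.175, 0.177 and 0.206 for the second. By the first pairing, the shared SE is too small for the strain labelled double null and too large for the others. Calls are then favoured in the strain labelled double null and held back in the others. In the strain labelled gcr1 null, arrays 1 and 3 and arrays 2 and 4 correlated at 0.818 and 0.814, and arrays 1 and 4 and arrays 2 and 3 at 0.716 and 0.707. In the nup84 null the same pairs correlated at 0.741 and 0.735 against 0.575 and 0.656. The strain labelled double null gave 0.826 and 0.748 against 0.469 and 0.673. If arrays 1 and 4 were swaps, the first pairing would mix samples and have the smaller difference. It had the larger difference in all 3 strains, which argues against arrays 1 and 4 as swaps. If arrays 1 and 3 are the true swaps, the second pairing averages over biological samples and understates the variance, which raises its counts. Values given for sample 1 are means of arrays 1 and 3, and those for sample 2 are means of arrays 2 and 4.

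Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 3 strains in 1 fit and 3 residual degrees of freedom before moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 5636 genes. The contrasts were each strain against wild type, the differences between strains, and the strain labelled double null minus the sum of both single-deletion strains. The ratio to wild type was tested against 0. Gene lists were tested with camera of limma at a preset correlation of 0.01, again keeping the larger p-value, with adjustment over 185 tests of 37 lists and 5 contrasts. The preset correlation gave 95 tests past the threshold and an estimated correlation gave 0, with a lowest adjusted p of 0.695. Member counts adjusted over the list alone used the members' own p-values. Whether probes tell genes of similar sequence apart was not checked, so member counts of any list may repeat a shared signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

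The lists, the tests and the rule for named genes were fixed before the data were examined. For each strain the rule took GCR1, NUP84, and the 10 largest increases and decreases among called genes that moved in the same direction on all 4 arrays. It also took up to 2 highest and 2 lowest members of each list. Between strains it took the 5 largest called differences in each direction or, where no gene was called, the 5 of lowest p-value in each direction. Genes named outside this rule are said to have been chosen after their values were seen.

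The tests were tried on simulated data in which 200 of 5636 genes were changed, with arrays 1 and 3 as true swaps. For the strain labelled gcr1 null, 41.8% of genes changed by 1 on the log2 scale were recovered, 92.5% of those changed by 2 and 100% of those changed by 4. For the strain labelled double null minus the strain labelled gcr1 null the recovered shares were 7.46%, 49.3% and 97.0%. For the gcr1 comparison 0.147% of unchanged genes were called. The simulations gave all 3 strains the same noise, while in the data the samples of the strain labelled double null differed most under the first pairing. The recovered shares and the share of unchanged genes called therefore hold for equal noise and may differ in these data. The number of arrays limits the precision of every value. Alternatives covered the pairing, arrays as replicates with a dye term, the replicate number as a block, centring, scale normalization, missing values, probes per gene, variance moderation, the 10% most variable genes, a fold limit, left-out pairs of arrays, and the list test. Leaving out the 10% most variable genes also takes them out of the lists, so a list can then have fewer members.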

Results

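Transcript levels of 5636 yeast genes were compared between deletion strains and wild type on 12 arrays. Gcr1 is a transcriptional activator known for its glycolytic and ribosomal protein gene targets, and Nup84 is a scaffold subunit of the nuclear pore complex. The strains were labelled gcr1 null, nup84 null and nup84 gcr1 double null, with 4 arrays and 2 biological samples each. The comparisons ask how each deletion changes transcript levels and how the combined deletion relates to each alone. All values are log2 ratios of deletion strain over wild type, with the standard error (SE) from limma, which is moderated, pools the spread of 2 biological samples over all 3 strains and is the larger of 2 fits, so that it is not the spread within a single strain. Within a strain, arrays correlated across genes at 0.707 to 0.891 in the strain labelled gcr1 null, 0.575 to 0.852 in the nup84 null and 0.469 to 0.826 in the strain labelled double null.

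The deleted genes were read first as a check of the labels. NUP84 (YDL116W) fell in both strains labelled as lacking it, to a log2 ratio of -3.19 ± 0.24 in the nup84 null (SE, n = 2; adjusted p = 0.000549) and -2.74 ± 0.24 in the strain labelled double null (adjusted p = 0.000128). In the strain labelled gcr1 null, NUP84 read -0.49 (adjusted p = 0.155). GCR1 (YPL075W) went against its label. It rose to 1.08 ± 0.21 in the strain labelled gcr1 null (adjusted p = 0.00453) and to 0.78 ± 0.21 in the strain labelled double null (adjusted p = 0.0174), and read 0.47 in the nup84 null (adjusted p = 0.158). Both GCR1 probes averaged 1.08 in the strain labelled gcr1 null, with arrays from 0.83 to 1.38. The position of these probes in the gene is not given in the sources used here, and a probe outside the deleted part would check nothing. Both strains are therefore named by their labels, and the deletion of GCR1 in them rests on those labels. Genes of glycolysis and fermentation, among them known Gcr1 targets, fell more there than in the nup84 null. Of 21 such genes, 15 fell and 3 rose in each strain labelled as lacking GCR1, against 4 and 2 in the nup84 null. Their medians were -1.43 and -1.94 against -0.76. These falls go with a loss of Gcr1 function but do not show which gene was deleted. The direction of the ratio in the strain labelled double null also has the fall of NUP84 behind it. In the strain labelled gcr1 null the direction rests on the labels, though its changes ran with those of the strain labelled double null at r = 0.911 across genes. The GCR1 increase did not pass without arrays 2 and 4, 1 and 4, or 2 and 3 of the strain labelled gcr1 null (0.90, 1.11 and 1.06; adjusted p = 0.138, 0.072 and 0.0796) or without arrays 2 and 4 of the strain labelled double null (0.69; adjusted p = 0.0512). Without arrays 1 and 4 of the nup84 null, NUP84 read -3.01 (adjusted p = 0.0521).

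In the strain labelled gcr1 null, transcripts of several glycolytic enzymes fell. ENO2 and ENO1, which encode the enolases, fell to -5.53 ± 0.23 and -4.24 ± 0.41 (SE, n = 2), which is 46.3-fold and 18.9-fold below wild type. GPM1, encoding phosphoglycerate mutase, fell to -5.15 ± 0.27, and TPI1, encoding triose phosphate isomerase, fell to -3.19 ± 0.35. GPM2, a homologue of GPM1, rose to 5.05 ± 0.27. Of the 21 measured genes of glycolysis and ethanol fermentation, 15 fell and 3 rose, and the same counts were obtained when adjusted over the list alone. The risers included HXK1, the glucose-repressed hexokinase gene, at 4.31 ± 0.37, and GLK1, encoding glucokinase, at 2.81 ± 0.38. The list median was -1.43 (adjusted p = 0.00199; adjusted p = 0.781 with an estimated correlation). When the 10% most variable genes were left out the median was -0.76 and the list did not pass (adjusted p = 0.495). Members of the list were among the genes left out, so this is a test of a smaller list.

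**Figure D1:**
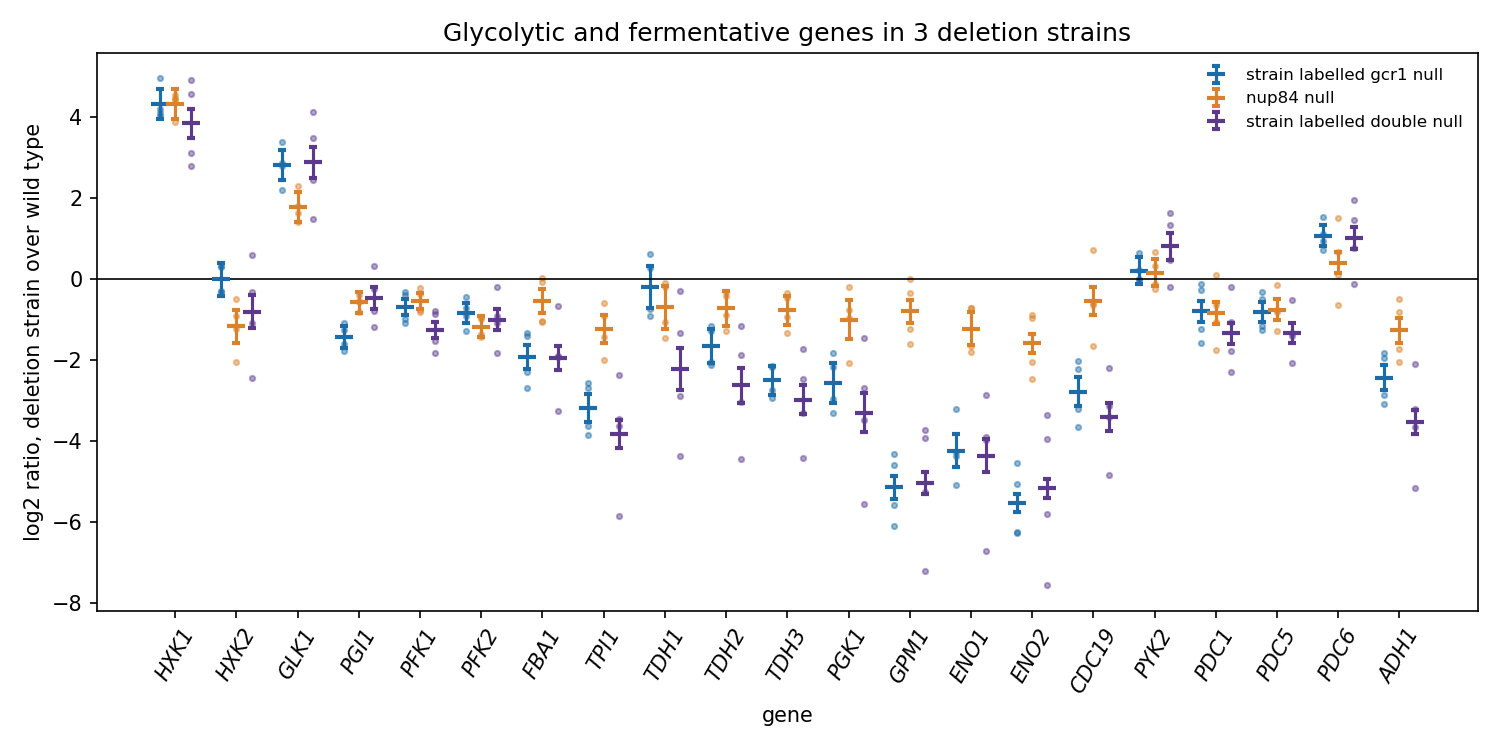
Log2 ratio over wild type (vertical axis) of 21 genes of glycolysis and ethanol fermentation (horizontal axis) in 3 strains. Dots are the 4 arrays of a strain, wide dashes their mean and bars the moderated SE pooled over strains; ENO2 and GPM1 lie below -5 in the strains labelled gcr1 null and double null, and HXK1 lies near 4 in all 3 strains.

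Genes of the translation machinery fell as a group in the strain labelled gcr1 null. Of 136 genes for cytosolic ribosomal proteins, 135 fell and none rose, with a median of -2.27 (adjusted p = 2.7e-31; adjusted p = 0.695 with an estimated correlation). Adjusted over the list alone the count was also 135. The lowest were RPL9A at -3.30 ± 0.24, RPS26B at -2.99 ± 0.23 and RPL20A at -2.95 ± 0.26. Of 99 ribosome biogenesis genes, 70 fell, or 75 adjusted over the list alone, among them BRX1 at -2.18 ± 0.25 and CIC1 at -2.17 ± 0.41, both assembly factors of the large subunit. Their median was -1.18 (adjusted p = 2.95e-18; adjusted p = 0.695 with an estimated correlation). Of 38 genes for translation initiation and elongation, 28 fell and 1 rose, also when adjusted over the list alone, with HYP2, encoding eIF5A, at -1.78 ± 0.25. Of 27 subunit genes of RNA polymerases I and III, 15 fell, also over the list alone. The medians of these lists were -1.10 and -0.90 (adjusted p = 4e-08 and 2.04e-05; adjusted p = 0.695 with an estimated correlation for both).

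Genes of respiratory and non-fermentable carbon metabolism rose in the same strain. Of 19 genes of gluconeogenesis and the glyoxylate cycle 16 rose, including ALD4, the mitochondrial aldehyde dehydrogenase gene, at 3.25 ± 0.24 and JEN1, the lactate and pyruvate permease gene, at 2.76 ± 0.21. Adjusted over the list alone 16 rose, and the median was 1.54 (adjusted p = 1.11e-05; adjusted p = 0.695 with an estimated correlation). Of 18 TCA cycle genes 15 rose, or 17 adjusted over the list alone, with the citrate synthase genes CIT3 at 3.40 ± 0.23 and CIT1 at 3.18 ± 0.29. Of 39 genes of the respiratory chain and ATP synthase 30 rose, or 33 adjusted over the list alone, with CYB2, encoding lactate dehydrogenase, at 3.21 ± 0.27. Their medians were 1.27 and 1.07 (adjusted p = 1.28e-06 and 2.37e-10; adjusted p = 0.695 and 0.708 with an estimated correlation). Samples 1 and 2 were unequal, with medians of 1.56 and 0.89 for TCA cycle genes and 1.42 and 0.73 for respiratory genes. PET122, a translational activator of a mitochondrial mRNA, fell to -4.50 ± 0.24.

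Storage carbohydrate and stress genes rose as well. Of 20 genes of trehalose and glycogen metabolism, 17 rose and 1 fell (19 and 1 adjusted over the list alone), with GPH1, the glycogen phosphorylase gene, at 2.88 ± 0.22 and GLC3, the branching enzyme gene, at 2.80 ± 0.40. Of 46 general stress response genes, 32 rose and 1 fell (33 and 2 adjusted over the list alone). HSP12, encoding a small heat shock protein, reached 5.37 ± 0.31 and NCE103, encoding carbonic anhydrase, 3.65 ± 0.54, while ALD6, the cytosolic aldehyde dehydrogenase gene, fell to -2.64 ± 0.22. The medians were 1.41 and 1.48 (adjusted p = 4.48e-06 and 1.3e-07; adjusted p = 0.695 with an estimated correlation for both). Of 11 histone genes 9 fell, also over the list alone, including HTB2 at -2.22 ± 0.27 and HTA1 at -1.83 ± 0.26, with a median of -1.50 (adjusted p = 0.000153; adjusted p = 0.708 with an estimated correlation). The highest ratio of any called gene was that of GCN4, the activator of amino acid synthesis genes, at 6.93 ± 1.02. The ratio does not tell a high level in the deletion strain from a low level in the wild type. The vitamin B6 genes SNZ1 and SNO1 rose to 4.64 ± 0.36 and 3.79 ± 0.27, while CHA1, the serine and threonine deaminase gene, and LYS9, a lysine synthesis gene, fell to -4.32 ± 0.36 and -3.34 ± 0.26.

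DNA damage and phosphate genes did not pass as lists in the strain labelled gcr1 null, and glucose transporter and nuclear pore genes did. Of 24 DNA damage response genes 5 rose and 3 fell (5 and 1 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.317). Of 18 phosphate regulon genes 3 rose and 2 fell (1 and 1 adjusted over the list alone), with a median of -0.03 and a mean of the other sign, 0.02 (adjusted p = 0.834). Of 22 glucose transporter and sensor genes 6 rose, also over the list alone, with a median of 0.51 (adjusted p = 0.00955; adjusted p = 0.695 with an estimated correlation). Among 33 nuclear pore genes 5 fell and 1, POM33, rose to 1.52 ± 0.32 (2 and 1 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.0394; adjusted p = 0.724 with an estimated correlation). That list did not pass without arrays 1 and 3, 1 and 4, or 2 and 3 of this strain (adjusted p = 0.197, 0.0896 and 0.0562), nor when the 10% most variable genes were left out (adjusted p = 0.0674).

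In all, limma called 1964 of 5636 genes in the strain labelled gcr1 null, 969 higher and 995 lower than wild type. The count was 4475 with arrays 1 and 4 and arrays 2 and 3 taken as the swaps. The spread of pair means argues against that pairing, which understates the variance wherever arrays 1 and 3 are the true swaps. The count was 3265 with the 4 arrays as replicates and 1204 with a limit of 2-fold. Without arrays 1 and 3, 2 and 4, 1 and 4, or 2 and 3 of this strain it was 896, 534, 576 and 640.

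In the nup84 null, stress and storage genes were among the largest increases. HSP12 rose to 5.70 ± 0.31 (SE, n = 2), which is 52.1-fold above wild type, and HSP26, another small heat shock protein gene, to 3.93 ± 0.32. GPH1 rose to 3.98 ± 0.22, the hexokinase gene HXK1 to 4.32 ± 0.37 and NCE103 to 3.58 ± 0.54. GCN4 read 4.46 ± 1.02 with unequal samples, 1.51 and 7.42. Of 46 general stress response genes 33 rose and 1 fell (35 and 1 adjusted over the list alone), with a median of 1.56. Of 20 trehalose and glycogen genes 14 rose (15 adjusted over the list alone), with a median of 1.44, including PGM2, the major phosphoglucomutase gene, at 2.64 ± 0.33. Both lists passed (adjusted p = 2.14e-12 and 1.69e-07; adjusted p = 0.695 with an estimated correlation for both). The high-affinity glucose transporter genes HXT7 and HXT6 rose to 3.68 ± 0.74 and 3.56 ± 0.73. Their samples were unequal, 5.56 and 1.79 for HXT7 and 5.49 and 1.64 for HXT6. Whether the probes tell these genes apart was not checked, so their values may repeat a shared signal. Of 22 glucose transporter and sensor genes 5 rose and 1 fell, also over the list alone, and the list with a median of 0.23 did not pass (adjusted p = 0.151).

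Translation genes fell in the nup84 null. Of 136 ribosomal protein genes 123 fell (134 adjusted over the list alone), with a median of -1.11 and RPL20A and RPL31A lowest at -1.70 ± 0.26 and -1.66 ± 0.24 (adjusted p = 1.03e-27 for the list; adjusted p = 0.695 with an estimated correlation). Of 99 ribosome biogenesis genes 23 fell (31 adjusted over the list alone), including the box C/D snoRNP genes NOP56 at -1.47 ± 0.27 and NOP1 at -1.41 ± 0.22, and the median was -0.60 (adjusted p = 2.37e-10; adjusted p = 0.723 with an estimated correlation). Of 38 translation factor genes 16 fell (23 adjusted over the list alone) and of 27 RNA polymerase I and III genes 8 fell (10 adjusted over the list alone). Their medians were -0.73 and -0.49 (adjusted p = 6.21e-08 and 0.00039; adjusted p = 0.695 and 0.708 with an estimated correlation). Of 11 histone genes 7 fell (9 adjusted over the list alone), with HTB2 at -1.77 ± 0.27 and HTA1 at -1.62 ± 0.26 and a median of -1.16 (adjusted p = 0.000248; adjusted p = 0.708 with an estimated correlation).

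Carbon metabolism lists shifted in the nup84 null too. Of 21 glycolysis and fermentation genes 4 fell and 2 rose (10 and 2 adjusted over the list alone), with ENO2 at -1.59 ± 0.23, the alcohol dehydrogenase gene ADH1 at -1.27 ± 0.30 and GLK1 at 1.78 ± 0.38. The list median was -0.76 (adjusted p = 0.00442; adjusted p = 0.818 with an estimated correlation), and with the 10% most variable genes left out the list did not pass (median -0.56; adjusted p = 0.526). Of 19 gluconeogenesis and glyoxylate cycle genes 13 rose (16 adjusted over the list alone), with the NADP isocitrate dehydrogenase gene IDP2 at 2.37 ± 0.22, and the median was 1.07 (adjusted p = 4.93e-06; adjusted p = 0.695 with an estimated correlation). Of 18 TCA cycle genes 4 rose (7 adjusted over the list alone), with LSC2, a succinyl-CoA ligase gene, at 1.66 ± 0.23, and of 39 respiratory chain genes 7 rose, also over the list alone, with CYC7, a cytochrome c gene, at 1.99 ± 0.38. Their medians were 0.62 and 0.40 (adjusted p = 0.000162 and 9.56e-05; adjusted p = 0.724 and 0.8 with an estimated correlation).

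The DNA damage response list rose in the nup84 null. Of its 24 genes 11 rose and none fell (15 adjusted over the list alone), including the ribonucleotide reductase genes RNR4 at 1.93 ± 0.27 and RNR2 at 1.66 ± 0.32. The median was 0.75 (adjusted p = 0.000345; adjusted p = 0.695 with an estimated correlation). Of 18 phosphate regulon genes 3 rose, also over the list alone, with the nucleotidase gene PHM8 at 2.03 ± 0.35 and the phosphate transporter gene PHO89 at 1.43 ± 0.33, and the median was 0.51 (adjusted p = 0.00955; adjusted p = 0.724 with an estimated correlation). Among 33 nuclear pore genes 1 fell, NUP84 itself, also over the list alone, and the median was -0.17 (adjusted p = 0.24). After NUP84 the largest decreases were those of FRE4, a ferric reductase family gene, at -2.15 ± 0.21, YOL014W at -2.03 ± 0.29 and SUN4, a cell wall gene of septation, at -2.02 ± 0.27.

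Limma called 941 genes in the nup84 null, 485 higher and 456 lower. The count was 4192 with arrays 1 and 4 and arrays 2 and 3 as the swaps, 2599 with the 4 arrays as replicates, 1923 after scale normalization, 588 with a limit of 2-fold and 1893 without any pair of arrays of the strain labelled double null. Without arrays 1 and 3, 2 and 4, 1 and 4, or 2 and 3 of the nup84 null itself it was 33, 5, 6 and 4.

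In the strain labelled double null, glycolytic transcripts fell and stress and gluconeogenic transcripts rose. ENO2, GPM1 and ENO1 fell to -5.17 ± 0.23, -5.03 ± 0.27 and -4.36 ± 0.41 (SE, n = 2), and TPI1, ADH1 and the pyruvate kinase gene CDC19 to -3.83 ± 0.35, -3.53 ± 0.30 and -3.40 ± 0.35. Of 21 glycolysis and fermentation genes 15 fell and 3 rose (15 and 4 adjusted over the list alone), with a median of -1.94 (adjusted p = 0.000513; adjusted p = 0.724 with an estimated correlation). The median differed between samples 1 and 2, at -1.17 and -2.59. The list did not pass with the 10% most variable genes left out (median -0.74; adjusted p = 0.586). Of 19 gluconeogenesis and glyoxylate cycle genes 17 rose (18 adjusted over the list alone), including ADH2, the ethanol-oxidising alcohol dehydrogenase gene, at 4.74 ± 0.27 and ALD4 at 4.23 ± 0.24. The median was 2.26 (adjusted p = 5.65e-07; adjusted p = 0.695 with an estimated correlation). TCA cycle and respiratory genes rose in 17 of 18 and 36 of 39 cases, also over each list alone, with CIT3 at 4.95 ± 0.23 and the ATP synthase gene ATP3 at 2.22 ± 0.24. Their medians were 1.29 and 1.18 (adjusted p = 1.28e-06 and 2.37e-10; adjusted p = 0.695 and 0.708 with an estimated correlation). Samples 1 and 2 were unequal, with medians of 1.78 and 0.73 for TCA cycle genes and 1.64 and 0.77 for respiratory genes.

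Stress genes of the strain labelled double null were led by HSP12 at 6.55 ± 0.31 and HSP26 at 5.38 ± 0.32, which are 93.4-fold and 41.6-fold above wild type. Of 46 general stress response genes 38 rose and 1 fell (39 and 1 adjusted over the list alone), with a median of 2.13, and of 20 trehalose and glycogen genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.51. Both lists passed (adjusted p = 3.33e-10 and 6.18e-06; adjusted p = 0.695 with an estimated correlation for both). Of 136 ribosomal protein genes 134 fell (135 adjusted over the list alone), with RPL9A at -3.39 ± 0.24 and a median of -2.10 (adjusted p = 7.55e-29; adjusted p = 0.695 with an estimated correlation). Of 99 ribosome biogenesis genes 80 fell (89 adjusted over the list alone), of 38 translation factor genes 28 fell (31 adjusted over the list alone), and of 27 RNA polymerase I and III genes 18 fell and 1 rose (19 and 1 adjusted over the list alone). Their medians were -1.42, -1.11 and -0.94 (adjusted p = 5.83e-21, 5.12e-09 and 7.97e-05; adjusted p = 0.695 with an estimated correlation for all 3). Medians of samples 1 and 2 were unequal, at 2.60 and 1.74 for general stress genes and -1.93 and -0.93 for ribosome biogenesis genes. GCN4 read 7.12 ± 1.02, and SNZ1 rose to 5.24 ± 0.36 and PDH1, a mitochondrial propionate metabolism gene, to 5.33 ± 0.20.

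The phosphate regulon rose in the strain labelled double null. Of its 18 measured genes 13 rose and none fell, also over the list alone, with a median of 1.15 (adjusted p = 3.98e-05; adjusted p = 0.695 with an estimated correlation). The list medians of samples 1 and 2 were unequal, at 1.71 and 0.81. PHO5, the repressible acid phosphatase gene, rose to 4.44 ± 0.41 and PHO89 to 3.53 ± 0.33. The phosphate transporter gene PHO84 and the transport regulator gene SPL2, chosen after their values were seen, rose to 2.87 ± 0.27 and 2.31 ± 0.32. Of 11 histone genes 7 fell, also over the list alone, with a median of -1.03 (adjusted p = 0.00955; adjusted p = 0.796 with an estimated correlation), and the list did not pass without arrays 2 and 4 of this strain (adjusted p = 0.0768). Of 33 nuclear pore genes 9 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.56 (adjusted p = 0.00184; adjusted p = 0.695 with an estimated correlation), which did not pass without arrays 1 and 3 of this strain (-0.24; adjusted p = 0.18). Of 24 DNA damage response genes 6 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.153). Of 22 glucose transporter and sensor genes 6 rose and 1 fell, also over the list alone, with a median of 0.53 (adjusted p = 0.0132; adjusted p = 0.695 with an estimated correlation). That list did not pass without arrays 1 and 3 (adjusted p = 0.0969) or with the 10% most variable genes left out (adjusted p = 0.139).

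**Figure D2:**
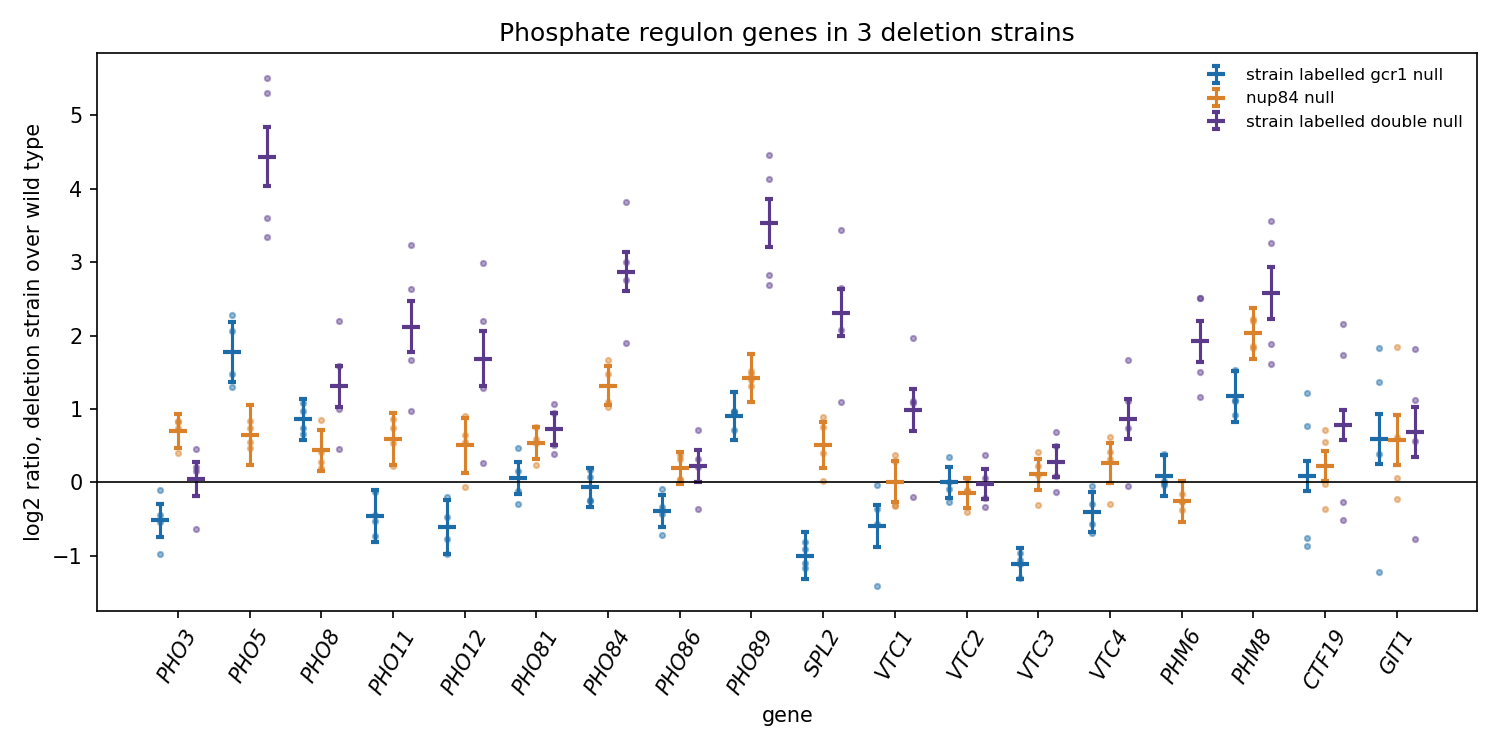
Log2 ratio over wild type (vertical axis) of 18 phosphate regulon genes (horizontal axis) in 3 strains. Dots are the 4 arrays of a strain, wide dashes their mean and bars the moderated SE pooled over strains; PHO5, PHO84, PHO89 and SPL2 are highest in the strain labelled double null.

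Limma called 2224 genes in the strain labelled double null, 1156 higher and 1068 lower. Samples of this strain differed most under the first pairing, so the SE pooled over strains favours calls here, and counts of the strains are not directly comparable. The count was 4629 with arrays 1 and 4 and arrays 2 and 3 as the swaps, 3432 with the 4 arrays as replicates and 1358 with a limit of 2-fold.

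**Figure D3:**
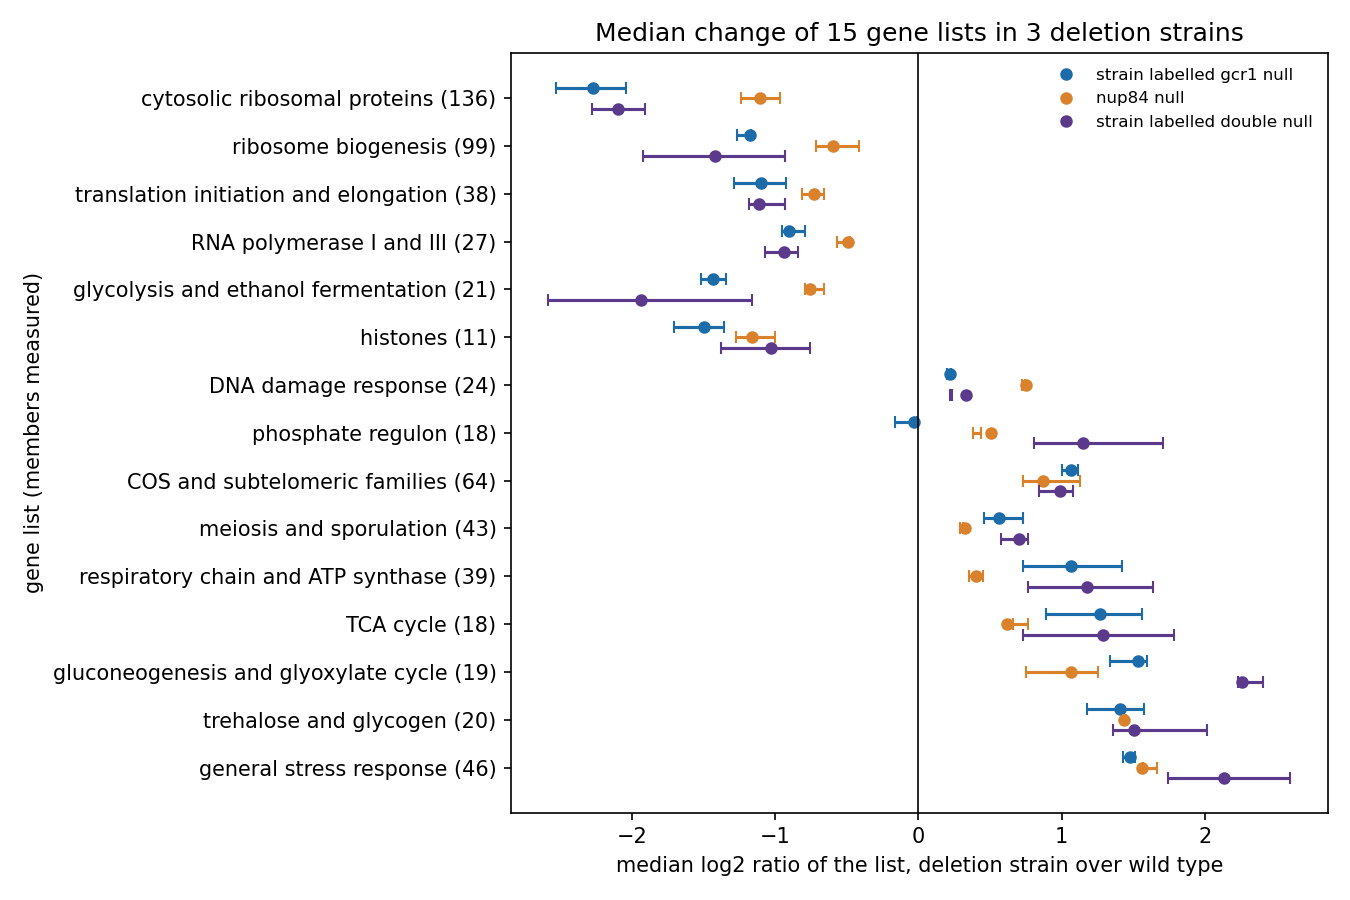
Median log2 ratio over wild type (horizontal axis) of 15 gene lists (vertical axis, with the number of measured members) in 3 strains. Dots are medians of the mean ratios over 4 arrays, and lines join the medians of the 2 pair means (arrays 1 and 3, arrays 2 and 4), which need not enclose the dot; ribosomal protein genes lie between -2.27 and -1.11 and general stress genes between 1.48 and 2.13.

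The single-deletion strains were compared with each other to ask which transcripts respond differently to each deletion. No list was tested in this contrast. The glycolytic genes GPM1 and ENO2 were higher in the nup84 null than in the strain labelled gcr1 null, GPM1 by 4.34 ± 0.39 (adjusted p = 0.00612) and ENO2 by 3.94 ± 0.32 (adjusted p = 0.00623), with PET122 higher by 3.76 ± 0.34. Lower in the nup84 null were CIT2, the peroxisomal citrate synthase gene, at -3.23 ± 0.39, the dicarboxylic amino acid permease gene DIP5 at -3.01 ± 0.35 and the dihydroxyacetone kinase gene DAK2 at -2.98 ± 0.31. A few genes moved in opposite directions in these strains. IMD2, an IMP dehydrogenase gene, stood at 2.30 in the strain labelled gcr1 null and -1.54 in the nup84 null, and RNR4 at -0.97 and 1.93. The ammonium assimilation genes GLN1 and GLT1, chosen after their values were seen, were lower in the nup84 null by 2.35 and 2.09, with GLN1 at 1.65 and -0.70.

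Limma called 29 genes between the single-deletion strains, 7 higher and 22 lower in the nup84 null. After scale normalization it called 46, of which 22 were higher and 24 lower. Without 1 pair of arrays the count was 3, 5, 0 and 4 for the strain labelled gcr1 null, 0, 1, 0 and 0 for the nup84 null and 423 for any pair of the strain labelled double null. The count was 3149 with arrays 1 and 4 and arrays 2 and 3 as the swaps, 902 with the 4 arrays as replicates and 100 with the 10% most variable genes left out.

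Across 5636 genes the mean changes of the single-deletion strains ran together, with Pearson r = 0.786, Spearman rho = 0.776 and 79.0% of genes of the same sign. Genes are not independent replicates, so no p-value was taken from them. The covariance was 0.486. In 100 simulations of unchanged strains that shared their wild-type RNA, r averaged 0.497 with a highest value of 0.534, and the covariance averaged 0.0449 with a highest value of 0.0506. The simulations gave wild-type and deletion-strain RNA equal noise, which by itself sets r near that value. More noise in the wild type would raise r, so the simulated r marks no ceiling for shared controls. The labels do not say whether wild-type RNA was shared, and part of the excess may come from shared controls. Of the called genes, 383 rose and 396 fell in both strains, where independent lists would share 83.4 and 80.5, and 8 were called in opposite directions, against 164. Those expectations leave shared controls out of account, and the simulations, in which hardly any unchanged gene can be called, shared 0 calls and so set no reference for the overlap. The strain labelled double null correlated with the strain labelled gcr1 null at r = 0.911 and with the nup84 null at r = 0.781. The simulations, again with equal noise, gave a mean of 0.501 for both and highest values of 0.547 and 0.548, which are no ceiling either.

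**Figure D4:**
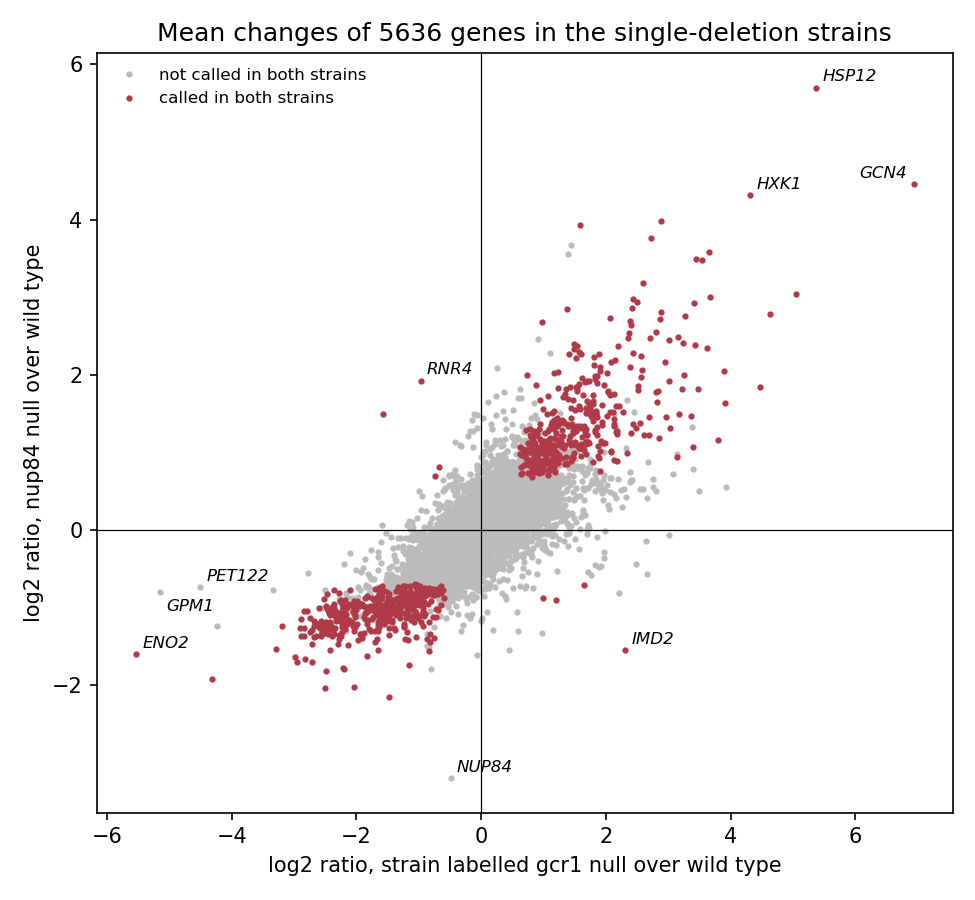
Mean log2 ratios over wild type of 5636 genes in the strain labelled gcr1 null (horizontal axis) and the nup84 null (vertical axis). Each point is 1 gene, red where it was called in both strains; HSP12 and GCN4 lie at the upper right and ENO2 at the lower left.

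The strain labelled double null was then set against each single-deletion strain. Relative to the nup84 null it had lower glycolytic transcripts, with GPM1 at -4.23 ± 0.39, ENO2 at -3.58 ± 0.32 and CDC19 at -2.85 ± 0.50, and higher CIT3 at 4.17 ± 0.33, PHO5 at 3.79 ± 0.57 and ADH2 at 3.75 ± 0.38. Of 21 glycolysis and fermentation genes 3 were lower (10 adjusted over the list alone), with a median difference of -1.40 (adjusted p = 0.00216; adjusted p = 0.708 with an estimated correlation). That list did not pass without arrays 2 and 4 of the strain labelled double null (-0.62; adjusted p = 0.0942) or with the 10% most variable genes left out (-0.19; adjusted p = 0.807). Ribosomal protein genes differed by a median of -1.02, with 0 of 136 called over all genes and 101 lower adjusted over the list alone (adjusted p = 2.95e-25; adjusted p = 0.695 with an estimated correlation). Gluconeogenesis and glyoxylate cycle genes differed by 1.14, with 4 of 19 higher (10 adjusted over the list alone), and respiratory genes by 0.73, with 0 of 39 called (6 adjusted over the list alone). These lists passed (adjusted p = 9.82e-06 and 4.89e-10; adjusted p = 0.695 and 0.708 with an estimated correlation).

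Limma called 42 genes between the strain labelled double null and the nup84 null, 36 higher and 6 lower. The count was 0 after scale normalization, 137 with the 10% most variable genes left out, 1222 with the 4 arrays as replicates and 3582 with arrays 1 and 4 and arrays 2 and 3 as the swaps. Without 1 pair of arrays it was 0, 1, 0 and 0 for the nup84 null, 132, 1142, 177 and 229 for the strain labelled double null and 23 for any pair of the strain labelled gcr1 null.

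Relative to the strain labelled gcr1 null, the strain labelled double null had no gene past the threshold. This does not show that the strains are alike. NUP84, by the labels deleted in only 1 of them, was missed as well. Simulated changes of 1 and 2 were recovered for 7.46% and 49.3% of genes, with equal noise in all strains. The genes of lowest p-value, none of which passed, were HSP26 at 3.79 ± 0.46, SPL2 at 3.31 ± 0.45, PHO84 at 2.94 ± 0.38 and the aromatic amino acid catabolism genes ARO9 at 2.72 ± 0.38 and ARO10 at 2.37 ± 0.31 (adjusted p = 0.068 for all 5), and on the other side NUP84 at -2.25 ± 0.34 (adjusted p = 0.106). As a list, the phosphate regulon was higher by a median of 1.40, with 0 of 18 genes called over all genes and 11 higher adjusted over the list alone (adjusted p = 1.15e-11; adjusted p = 0.695 with an estimated correlation). It was also higher than in the nup84 null, by 0.74, with 1 of 18 called (6 adjusted over the list alone; adjusted p = 3.09e-05; adjusted p = 0.695 with an estimated correlation). General stress genes were higher than in the strain labelled gcr1 null by 0.71, with 0 of 46 called and 2 adjusted over the list alone, and gluconeogenesis genes by 0.71, with 0 of 19 called and 4 adjusted over the list alone. Both passed (adjusted p = 8.18e-12 and 1.19e-05; adjusted p = 0.695 with an estimated correlation for both). Without arrays 1 and 3 of the strain labelled double null, the stress list stood at 0.24 (adjusted p = 0.0515).

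Glycolysis and ribosomal protein lists had small median differences between these strains. Their medians were -0.48 and 0.12, with 0 genes called in either list, also over each list alone (adjusted p = 0.00832 and 0.00638; adjusted p = 0.836 and 0.919 with an estimated correlation). The glycolysis median turned to 0.29 without arrays 2 and 4 of the strain labelled double null, and the list did not pass after scale normalization (-0.28; adjusted p = 0.303) or without the 10% most variable genes (adjusted p = 0.718). The ribosomal protein median turned to -0.13 without arrays 2 and 4 of the strain labelled gcr1 null and to -0.02 without arrays 1 and 3 of the strain labelled double null. It did not pass without arrays 1 and 4 of the strain labelled gcr1 null (adjusted p = 0.122) or arrays 2 and 3 of the strain labelled double null (adjusted p = 0.174). Limma called 0 genes between these strains, with 298 at an unadjusted p under 0.05. Because the larger of 2 p-values was kept, chance gives fewer than 281.8. With other settings it called 2340 (arrays 1 and 4 and arrays 2 and 3 as the swaps), 226 (4 arrays as replicates), 10 (10% most variable genes left out), 5 (trend and robust moderation), and 21, 138, 17 and 16 (without 1 pair of arrays of the strain labelled double null).

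The strain labelled double null was last compared with the sum of the single-deletion changes. Among the genes of lowest p-value, the stress gene HSP12, the hexokinase gene HXK1 and the glycogen phosphorylase gene GPH1 lay below that sum, at -4.53 ± 0.53, -4.80 ± 0.64 and -3.26 ± 0.39, and the histone gene HTB2 and ribosomal protein gene RPL19B lay above it, at 2.74 ± 0.47 and 2.26 ± 0.35. None passed (adjusted p = 0.0538 for HSP12 and GPH1, 0.0724 for HXK1 and 0.0731 for HTB2 and RPL19B). Limma called 0 genes, with 909 at an unadjusted p under 0.05, where chance gives fewer than 281.8. The absence of calls therefore does not show that the changes add up. A deviation of a shared wild type would enter both terms of the sum and could also put genes off it. The count was 623 after scale normalization, 82 with the 10% most variable genes left out, 1335 with the 4 arrays as replicates and 3627 with arrays 1 and 4 and arrays 2 and 3 as the swaps. Without 1 pair of arrays of the strain labelled double null it was 219, 716, 137 and 120, and without a pair of the others it was 0 or 1.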

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

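All tests of the patterns weighed in this part, those of dye, exchanged labels and remaining sequence for GCR1 and those of shared wild-type noise and of the growth and stress lists for the correlation, were chosen after the result was seen.

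In 5 of 154 groups of 4 arrays, 1 array lay far from the other 3, where chance flags about 1 in 20 groups, or 7.7 of 154. SPO20, a sporulation gene, read 2.51 on array 1 of the strain labelled gcr1 null and 3.28 to 3.42 on the others. In the nup84 null, HXK1 read 3.86 on array 4 against 4.43 to 4.54, and HSP26 read 3.73 on array 3 against 3.97 to 4.01. In the strain labelled double null, ALD4 read 4.71 on array 1 against 4.01 to 4.12, and URA3 read 2.28 on array 4 against 1.92 to 1.95.

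Responses differed between strains for 42 genes in the strain labelled double null against the nup84 null and for 29 genes in the nup84 null against the strain labelled gcr1 null. Among them, 5 genes were called in opposite directions in the single-deletion strains. The nup84 null minus the strain labelled gcr1 null gave -2.35 for GLN1 (adjusted p = 0.0128 by limma), -2.09 for GLT1 (0.0253), -3.85 for IMD2 (0.0411), 2.90 for RNR4 (0.0187) and 3.07 for YCL021W-A (0.0359). For another 3 genes called in opposite directions, CHO2, MCH5 and SAM3, the difference did not pass (adjusted p = 0.078, 0.0743 and 0.0743).

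Probes without a gene name carried signal too. Of 1448 such probes tested, 71 were called in the strain labelled gcr1 null and 63 in the strain labelled double null. In the nup84 null limma called 0 of them, with 139 at an unadjusted p under 0.05.

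GCR1 read above wild type in the strains labelled as lacking it. A dye effect would change sign between orientations, but the lowest of the 8 arrays of these strains read 0.53. An exchange of labels between the single-deletion strains would put the lower NUP84 in the strain labelled gcr1 null, but NUP84 was lower in the nup84 null by -2.70. A candidate explanation that stays open is GCR1 sequence left under the probes: both probes averaged 1.08, and their place relative to the deleted part is what keeps it open. No biological explanation was tested.

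The changes of the single-deletion strains ran together across genes. Noise between samples of a shared wild type would keep the covariance at or under 0.0523, the product of the SDs of the means as measured between samples, and the observed value was 0.486. If the growth, translation, stress and carbohydrate lists alone carried the relation, the covariance over the 5066 genes outside 13 such lists would stay at or under 0.0506, and it was 0.359. Wild-type RNA that deviated in the same way on all arrays stays open. A response common to both strains, such as slower growth, may underlie the relation as a hypothesis, and growth rates were not analysed here.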

How the results depend on the processing

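The replicate block on pair means was the only test in this part chosen after the data were seen. Of 1942 comparisons of a named gene with another setting, 1823 kept their side of the threshold, 20 lost it and 99 gained it, and of 2304 with a pair of arrays left out, 1847 kept it, 369 lost it and 88 gained it. Settings that change only the test leave the mean ratio and list median as they were, so their direction is no check. With the median of probes, a weaker rule on missing values, or arrays 1 with 3 and 2 with 4 paired, all 192 gene and all 67 list comparisons stayed the same. These settings could hardly differ from the main test, which nearly always kept the p-value of that pairing. Their share of the kept comparisons is therefore no sign of stability. Of 670 list comparisons under other settings, 64 no longer passed, most of them with an estimated correlation, under which 0 of 95 list tests passed. No centring moved no count by more than 1.5 times. The median of probes and the weaker rule on missing values gave the same counts, which was nearly fixed in advance. All 5636 genes had a value on every array, and median and mean can differ only for the 18 genes with 3 or 4 probes. The pairing of arrays 1 and 4 and arrays 2 and 3 understates the variance if arrays 1 and 3 are the true swaps. The spread of pair means argues against that pairing. Its counts were 4475, 4192 and 4629 for the strains labelled gcr1 null, nup84 null and double null. For double against gcr1, double against nup84 and nup84 against gcr1 they were 2340, 3582 and 3149, with 3627 off the sum. NUP84 in the strain labelled gcr1 null (-0.49; adjusted p = 0.00108) and GCR1 in the nup84 null (0.47; adjusted p = 0.000166) then passed. With the 4 arrays as replicates and a dye term, which overstates n, the counts in that order were 3265, 2599, 3432, 226, 1222, 902 and 1335, and GCR1 in the nup84 null passed (0.47). Scale normalization gave 1923 for the nup84 null, 0 for double against nup84, 46 for nup84 against gcr1 and 623 off the sum, with GCR1 in the nup84 null at 0.57 (adjusted p = 0.0406). Trend and robust moderation gave 5 for double against gcr1. Without the 10% most variable genes, which leaves 5072, the counts between strains were 10, 137, 100 and 82. A limit of 2-fold gave 1204, 588 and 1358, and took GCR1 in the strain labelled double null (0.78) off the calls. The cause was not tested.

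The array numbers were not taken to pair samples across strains, because the labels give them no such meaning. Deviations of same-numbered biological samples correlated at -0.00529 for gcr1 with nup84 and 0.0985 for nup84 with double, but at 0.552 for gcr1 with double, so a link between those samples is not ruled out. The replicate block over the 12 arrays gave 404 for double against gcr1, 1726 for double against nup84 and 1222 for nup84 against gcr1, and the replicate block on pair means gave 0, 71 and 43 in the same order.

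Leaving out 1 pair of arrays at a time, and so assuming that the remaining sample of that strain varies like the others, gave 534 to 2751 calls for the strain labelled gcr1 null, 4 to 1893 for the nup84 null, 1730 to 2531 for the strain labelled double null, 0 to 138 for double against gcr1, 0 to 1142 for double against nup84, 0 to 423 for nup84 against gcr1, 0 to 716 off the sum and 84 to 101 list shifts. GCR1 ranged from 0.90 to 1.26, 0.39 to 0.54 and 0.69 to 0.87 in the strains labelled gcr1 null, nup84 null and double null, and NUP84 from -0.51 to -0.47, -3.51 to -2.88 and -3.04 to -2.44. The correlation of the single-deletion changes ranged from 0.719 to 0.787. Some list medians turned or gained a pass. Glycolysis in double against gcr1 ranged from -0.89 to 0.29 and turned without arrays 2 and 4 of the strain labelled double null. Ribosomal protein genes in that contrast turned to -0.13 without arrays 2 and 4 of the strain labelled gcr1 null and to -0.02 without arrays 1 and 3 of the strain labelled double null. The Gcn4 list ranged from -0.54 to 0.015 in the nup84 null and from -0.58 to 0.032 in the strain labelled double null. The auxotrophic marker list, which passed nowhere, ranged from -0.361 to 0.585 in the strain labelled gcr1 null and turned without its arrays 1 and 3. In the nup84 null it ranged from -0.091 to 0.136 and turned to 0.051 without its arrays 1 and 3 and to 0.136 without its arrays 1 and 4. The number of arrays limits all of these values.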

Other observations

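All tests of the mating-type pattern in this part, those of dye, noise and shared wild-type cultures, were chosen after the result was seen.

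The list of COS and other subtelomeric gene families shifted upward in all 3 strains. Whether the probes tell members of a family apart was not checked, so counts of members may repeat a shared signal. Wild-type RNA that deviated in the same way on all arrays stays open here too. Of its 64 genes, 50 rose in the strain labelled gcr1 null (52 adjusted over the list alone), 34 in the nup84 null (40, with 1 lower) and 49 in the strain labelled double null, where 1 fell (52 and 1). The medians were 1.07, 0.87 and 0.99 (adjusted p = 3.14e-10, 1.83e-11 and 8.21e-09 by camera; adjusted p = 0.695, 0.695 and 0.708 with an estimated correlation). COS8 and COS7 rose to 3.92 ± 0.81 and 2.76 ± 0.55 in the strain labelled gcr1 null, and the flocculin gene FLO5 to 2.48 ± 0.33 in the strain labelled double null. In the nup84 null, AAD10, an aryl-alcohol dehydrogenase family gene, rose to 1.61 ± 0.27 and PAU1, a seripauperin gene, to 1.44 ± 0.23. Of 43 meiosis and sporulation genes, 19, 10 and 24 rose in the 3 strains in the same order (20, 16 and 27 adjusted over the list alone, with 1 lower in the nup84 null). SPS19, a peroxisomal dienoyl-CoA reductase gene induced in sporulation, rose to 3.67 ± 0.23 in the strain labelled gcr1 null and also rose in both others, and REC8, the meiotic cohesin gene, to 2.41 ± 0.23 in the strain labelled double null. The medians were 0.56, 0.33 and 0.70 (adjusted p = 3.55e-05, 0.0157 and 2.04e-05; adjusted p = 0.695 with an estimated correlation for all 3).

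Amino acid synthesis genes went both ways although GCN4 had among the highest ratios. GCN4 read 7.02 and 6.85 in the samples of the strain labelled gcr1 null, 7.10 and 7.15 in those of the strain labelled double null, and 1.51 and 7.42 in those of the nup84 null. Of 55 genes of the Gcn4 list, 10 rose and 15 fell in the strain labelled gcr1 null, 6 and 5 in the nup84 null and 12 and 14 in the strain labelled double null (10 and 16, 7 and 9, and 12 and 14 adjusted over the list alone). The list did not pass in any strain (adjusted p = 0.346, 0.195 and 0.317), with medians of -0.31, -0.23 and -0.29. The mean had the other sign in the strains labelled gcr1 null and double null, at 0.09 and 0.15, and was -0.02 in the nup84 null. The nup84 median turned to 0.015 without its arrays 1 and 3, and passed at -0.54 without its arrays 2 and 4 (adjusted p = 0.00104). In the strain labelled double null the median turned to 0.03 without arrays 2 and 4, and passed at -0.58 without arrays 1 and 3 (adjusted p = 0.022). The list of auxotrophic marker genes did not pass in any strain. Of its 8 genes, 2 rose and 1 fell in the strain labelled gcr1 null, 1 rose in the nup84 null, and 3 rose and 1 fell in the strain labelled double null, also over the list alone. The medians were 0.14, -0.05 and 0.39 (adjusted p = 0.687, 0.816 and 0.242), with a mean of the other sign in the nup84 null, 0.15. The first turned to -0.36 without arrays 1 and 3 of its strain, and the second to 0.05 and 0.14 without arrays 1 and 3 or 1 and 4 of the nup84 null. Among the genes that rose, URA3 and LEU2, which are often deleted or replaced in laboratory strains, reached 2.32 ± 0.21 and 1.72 ± 0.33 in the strain labelled gcr1 null and 2.02 ± 0.21 and 2.02 ± 0.33 in the strain labelled double null.

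Mating-type genes parted between the biological samples. Over 7 a-specific genes, such as MFA1, STE2 and STE6, samples 1 and 2 averaged -0.71 and 0.42 in the strain labelled gcr1 null, -1.40 and 0.78 in the strain labelled double null, and -0.07 and 0.78 in the nup84 null. Over 4 alpha-specific genes, such as STE3 and SAG1, they averaged 0.74 and -0.96, 0.96 and -1.33, and 0.31 and -0.11 in the same order. AGA2 went against the other a-specific genes in the strains labelled gcr1 null (0.56 and -0.08) and double null (0.33 and 0.18), as did MF(ALPHA)1 (-0.04 and 0.31) and MF(ALPHA)2 (-0.35 and -0.29) against the other alpha-specific genes in the nup84 null. The difference of alpha minus a genes between samples was 2.83, 1.27 and 4.47 in the strains labelled gcr1 null, nup84 null and double null. Between arrays of the same orientation a dye effect would leave 0, but the 6 such differences averaged 2.86 (SE 1.02), at 0.93, -0.03 and 2.17 on arrays 1 and 2 and 4.74, 2.56 and 6.77 on arrays 3 and 4. That mean restates the sample differences, in which the dyes are already balanced, so it adds no further evidence. Its SE counts swaps of the same samples as separate values. Cultures of unequal mating type may explain the pattern, which was not tested, and effects of single arrays, noise and a single pair of wild-type cultures shared by all strains stay open too. The largest and smallest strain differences were 3.21 apart with an SE over orientations of 2.64. That SE ignores that arrays 3 and 4 read higher than arrays 1 and 2 in every strain, so it cannot decide on shared cultures. Within orientations the strain labelled double null lay above the nup84 null, at 2.17 against -0.03 and 6.77 against 2.56. The percentile of 100 among 10000 random gene sets rests on co-regulated genes noticed in the same data.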
